A study of Caenorhabditis elegans with 3 samples.

How the data were processed

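RNA from L4 whole animals of 3 C. elegans strains was sequenced on an Illumina platform, 1 library per strain, per the labels. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase and made into messenger RNA libraries with an Illumina kit. Per the submitters' processing notes, FastQC, Bowtie2 (2.0.2), TopHat (1.3.1), SAMtools (0.1.16), Cufflinks (1.3.0) and Cuffdiff were used, with no role or order stated. The genome build and gene annotation are not given in the sources used here. Per the series design, each mutant was compared singly with wild type.

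The authors deposited 1 table per mutant with 45343 features, holding FPKM in the mutant and in wild type per the file headers. FPKM divides the fragments of a feature by its length and by the mapped fragments of the library, so it holds no counts, and a few abundant RNAs in a library lower the values of all others. Short features rest on few fragments and on a length correction that grows steep near the fragment length. The wild type values were identical in both tables for all 45343 features, so the 3 libraries were put side by side. The authors also deposited a p-value, a q-value and a status per feature, per the file headers. The status was OK for 16854 features in the ia03 table and 16646 in the ju145 table.

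The log2 ratio of FPKM + 1 between 2 libraries was computed for features with status OK and an FPKM of at least 1 in at least 1 of the libraries compared. The pseudocount of 1 understates the differences of low genes, and no fold is given where a value is listed at 0. A difference of at least 2-fold on this scale counted as a difference of size. Without replicates there is no p-value, standard deviation or test of a strain effect. For 31 gene lists the median log2 ratio was set among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. The random lists were not matched on length, so percentiles of lists of short genes may partly reflect length. Genes that differed from wild type in both mutants were counted beside the same count with each mutant as the odd library, the overlap of independent lists, and 200 simulations of 3 exchangeable libraries whose spread per gene came from the difference between the mutants.

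Before the data were examined, groups, lists, comparisons and the alternatives called planned were fixed, with a rule for the genes to name. That rule named ahr-1, the 12 highest and 12 lowest log2 ratios in each mutant, the 12 per direction with the largest smaller ratio in both, the 5 per direction between mutants, and up to 4 members of each list by size. It took mostly short RNAs listed at 0. The same rule was therefore also applied to coding genes and pseudogenes with at least 300 nt of exon in the longest reference transcript, and to those above 0 in all libraries, both chosen after the values were seen. The reference lengths may differ from those the authors used. The genes ctl-2, COX1, ATP6, ND5, mct-1, cylc-2, gcy-32, gcy-36, gcy-37 and F56D12.10 were also named after their values were seen. So were the other oxygen-sensing neuron genes below the floor.

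Of the features, 44880 matched the Ensembl release 115 annotation by sequence name, which gave biotypes and exon lengths. Symbols came from the files for 24967 features and from the reference for 2563, and the sequence name was kept for 17813. Coordinates are those of the files, counted from 1. The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a floor of FPKM 5, rescaling by the median ratio or by the upper quartile, all features whatever their status, leaving out stage-dependent lists, size limits of 1.5-fold and 4-fold, a q-value limit of 0.01, and the authors' call with the size rule, and, added after the data were seen, the longer coding genes and pseudogenes, genes above 0 in all libraries and other size limits between the mutants. On simulated data for both mutants against wild type, with 14230 genes of which 200 changed 4-fold, the size rule recovered 94% of the changed genes and took 0 others, with a spread between libraries set smaller than that seen. With no effect shared by the mutants and the spread seen between them, the same rule took on average 80.7 higher and 81.3 lower genes in both, so it does not exclude chance. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Relative depth was read from the ratio at which features with low FPKM clustered between libraries, and neither depth in counts nor counting intervals could be had from FPKM.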

Results

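Messenger RNA was measured by sequencing in whole Caenorhabditis elegans animals at the L4 larval stage. There were 3 strains, the wild type N2 and strains carrying the ia03 or the ju145 allele of ahr-1, the worm gene for the aryl hydrocarbon receptor, a transcription factor of the bHLH-PAS family. Each strain gave 1 library, so no value below has a replicate error and no difference was tested. The deposited tables held FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for 45343 features, of which 18698 were above 0 in the wild type library, 18411 in the ia03 library and 18603 in the ju145 library. Totals of mapped fragments were not used here. The lowest values of the ia03 library clustered at 0.810 of those of wild type for the same feature, and those of the ju145 library at 0.929. If such values are 1 fragment each, the ia03 library held 1.23 times and the ju145 library 1.08 times as many fragments as the wild type library.

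The targeted gene was read first, as a check of the strain labels. ahr-1 (C41G7.5, protein-coding, chromosome I, 9522570 to 9532823 in the coordinates of the files, whose genome build is not given in the sources used here) had an FPKM of 0.664 in wild type, 0.699 in ia03 and 0.569 in ju145. All 3 values lay below the floor of FPKM 1 used for the comparisons. The locus overlaps C41G7.8 and the far more abundant cylc-2 (FPKM of 112 in wild type), so the reads of ahr-1 are uncertain. A value for the whole gene does not show which part of it carries an allele, so these values neither bear out nor contradict the labels. The ARNT-like partner gene aha-1 had an FPKM of 9.51 in wild type, 11 in ia03 and 8.27 in ju145. No measured member of the ahr-1 pathway list differed by 2-fold in either mutant.

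The first comparison asked which transcripts of the ia03 animals differed from wild type. Sperm and yolk transcripts were lower in the ia03 library, several moulting genes were higher, and cuticle collagens differed in both directions. All 33 measured members of the list of major sperm proteins, the cytoskeletal proteins of nematode sperm, were below wild type. Their median log2 ratio was -0.84, and 8 were at least 2-fold lower, among them msp-52, msp-42 and msp-71, which are annotated as pseudogenes. Of the other sperm genes, 69 of 70 were below wild type, with a median of -0.70, 10 at least 2-fold lower and 1 at least 2-fold higher. All 6 vitellogenin genes, which encode yolk proteins, were below wild type (median -1.02), with vit-6 at FPKM 3301 in wild type and 1602 in ia03. Both sperm medians lay at percentile 0 of 10000 random lists matched on expression, and the vitellogenin median at percentile 0.17. The random lists were not matched on length. Genes with 200 to 300 nt of exon had medians of -0.67 in ia03 and -0.41 in ju145, and those with 300 to 500 nt -0.19 and -0.18. Length may therefore add to the low percentiles of lists of short genes in either mutant. Near-identical msp copies share reads, so the msp genes are not independent measurements. The loci of vit-3 and vit-4 each overlap another, more abundant feature, so their reads are uncertain too. The oocyte list (median -0.24, percentile 1.52) and the germline list (median -0.24, percentile 0.91) were also low, though no member of either was 2-fold lower.

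Among cuticle collagens in ia03, 9 of 132 were at least 2-fold higher and 9 at least 2-fold lower, and the list median of 0.12 lay at percentile 100. The FPKM of col-176 was 33.5 in wild type and 113 in ia03, that of dpy-3 was 27.1 and 84.2, that of dpy-10 was 29.5 and 80.0, and that of dpy-9 was 30.3 and 77.9. Of the moulting and cuticle matrix genes, 9 of 137 were at least 2-fold higher and 1 was lower (median 0.19, percentile 100). The fibrillin-related gene fbn-1 went from 9.56 in wild type to 27.5 in ia03, the hedgehog-related gene wrt-10 from 86.1 to 239 and noah-2 from 43.1 to 107. The pseudogene grl-32 was lower, at 45 in wild type and 16.6 in ia03.

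Genes of xenobiotic and lipid metabolism differed little in size in ia03. Of 48 cytochrome P450 genes, 31 were above wild type and 1 was 2-fold higher, cyp-13B1, at 3.52 in wild type and 11.2 in ia03 (list median 0.20, percentile 99.9). In fatty acid metabolism 54 of 82 genes were above wild type (median 0.13, percentile 100), with the lipase genes lipl-2 at 3.95 and 13.2 and lipl-6 at 2.94 and 8.80, and the acyl-CoA synthetase gene acs-7 at 11.3 and 26.3. The UDP-glucuronosyltransferases (median 0.06, percentile 92.5) and glutathione S-transferases (median 0.01, percentile 65.2) lay inside the central 95% of random lists. The lysozyme gene lys-7 had 11.2 in wild type and 35.9 in ia03, but its list had a median of -0.03, which turned positive under rescaling. Histone genes, many of them near-identical copies that share reads (median 0.28, percentile 100), and nuclear hormone receptor genes (median 0.10, percentile 99.8) were above wild type as lists. Heat shock genes were low (median -0.39, percentile 0.02), with hsp-70 at 24.7 in wild type and 11.2 in ia03 and hsp-16.11 at 600.5 and 293. The locus of hsp-70 overlaps uggt-2 in the files and hsp-16.11 has a second copy, so their reads are uncertain.

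Under the size rule, 372 genes were at least 2-fold higher in ia03 and 630 at least 2-fold lower, of 14783 genes measured. Among coding genes and pseudogenes of at least 300 nt, a subset chosen after the values were seen, the counts were 225 and 343. Of 31 lists, 30 had enough measured members for a percentile and 14 lay outside the central 95% of random lists.

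**Figure D1:**
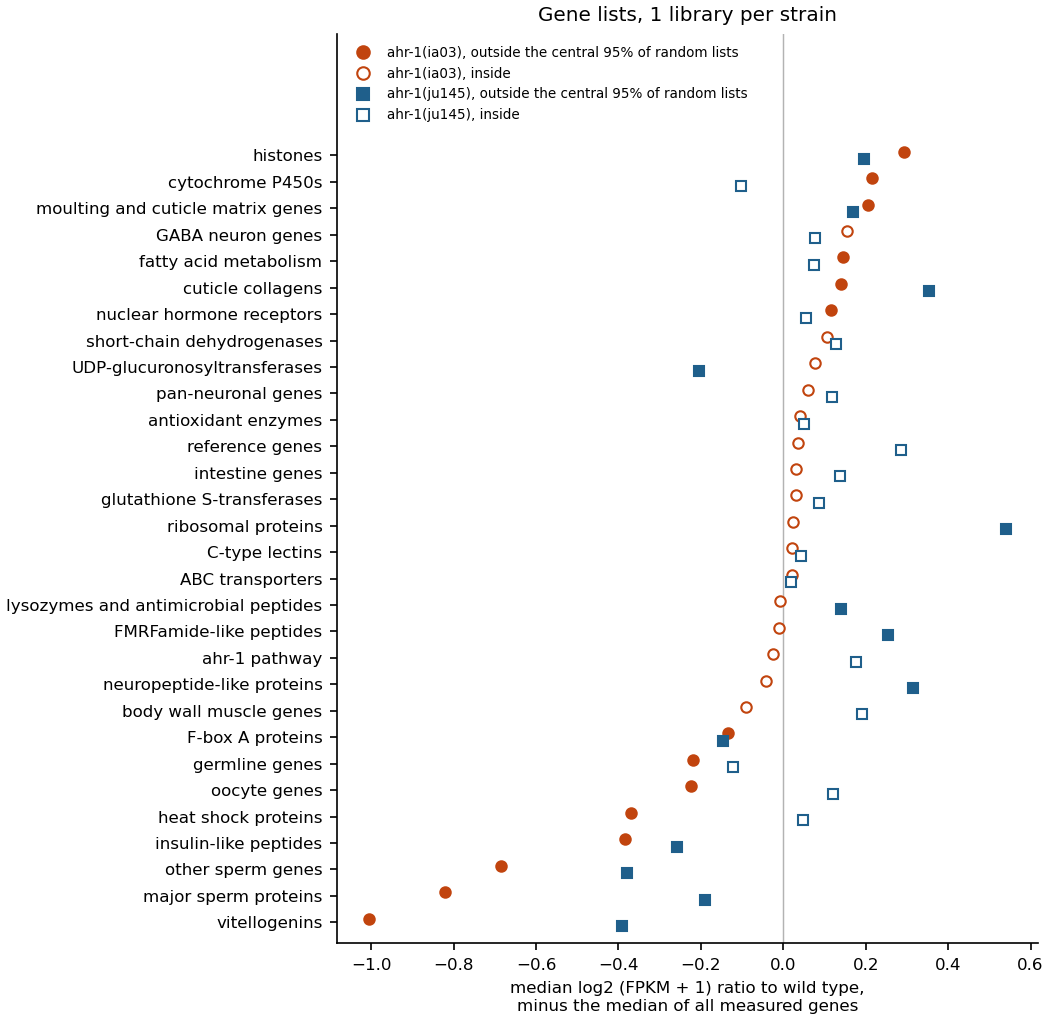
Median log2 ratio of FPKM + 1 to wild type for each list, minus the median of all measured genes, in the ia03 library (circles) and the ju145 library (squares); filled symbols lie outside the central 95% of 10000 random lists matched on expression. Vitellogenins lie at -1.01 in ia03 and -0.39 in ju145, and ribosomal proteins at 0.02 and 0.54.

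**Figure D2:**
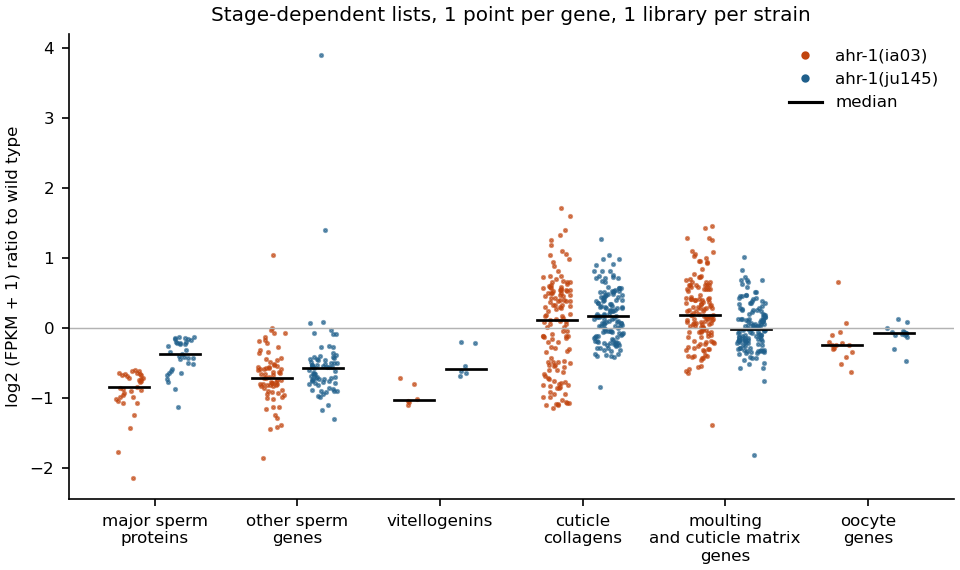
Log2 ratio of FPKM + 1 to wild type for each measured gene of 6 stage-dependent lists, with 1 point per gene and a line at the median, in the ia03 and ju145 libraries. All 33 members of the major sperm protein list, pseudogenes included, and all 6 vitellogenin genes lie below 0 in both.

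The second comparison asked the same of the ju145 animals. The median log2 ratio of all measured genes was -0.18 in ju145 against -0.02 in ia03, and 71.7% of them lay below wild type in ju145. List medians for ju145 are therefore given relative to that median. Ribosomal protein genes stood highest, with 67 of 70 above wild type and 69 above the median of all genes (relative median 0.54, percentile 100) and none at least 2-fold higher. For example, rpl-2 had an FPKM of 2972 in wild type and 4920 in ju145. Cuticle collagens (relative median 0.35, percentile 100), neuropeptide-like genes (0.31, percentile 100) and FMRFamide-like peptide genes (0.25, percentile 99.99) also stood above the median of all genes as lists. Of the 73 neuropeptide-like genes, though, 6 were at least 2-fold lower than wild type and 0 higher. Moulting genes had a median log2 ratio of -0.02 before and 0.17 after that adjustment (percentile 100), so their direction depends on the scaling. The collagen gene col-10 had 1241 in wild type and 2557 in ju145.

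Sperm and yolk transcripts were lower in ju145 as well. Of 33 major sperm protein genes 26 lay below the median of all genes, as did 63 of 71 other sperm genes and all 6 vitellogenin genes, with relative medians of -0.19, -0.38 and -0.39 and percentiles of 0, 0 and 0.37. At least 2-fold lower than wild type were 1 member of the major sperm protein list (the pseudogene msp-52), 3 of the other sperm genes and 0 of the vitellogenin genes. At least 2-fold higher were 2 other sperm genes. The UDP-glucuronosyltransferases, enzymes of xenobiotic conjugation, had a relative median of -0.20 (percentile 0.02), with 37 of 51 below the median of all genes and none different by 2-fold. No measured cytochrome P450 gene differed by 2-fold (relative median -0.10, percentile 7.02). Single genes with large differences in ju145 were the saposin-like gene spp-31, at 23.6 in wild type and 3.13 in ju145, and the neuropeptide-like gene nlp-46, at 21.1 and 1.92. F-box A genes had a relative median of -0.15 (percentile 0.04) in ju145 and a median of -0.15 (percentile 0.25) in ia03, but both lay inside the central 95% when only genes with an FPKM of at least 5 were used, at percentiles 23.7 and 7.18. The GABA neuron and pan-neuronal lists, unlike the peptide lists in ju145, lay inside the central 95% in both mutants. GABA neuron genes lay at percentiles 88.8 in ia03 and 72.7 in ju145, and pan-neuronal genes at 76.5 and 92.8. The sign of the median in ju145 changed with rescaling for both of these lists. Of the 12 oxygen-sensing neuron genes, 2 reached the floor of FPKM 1. The FPKM of egl-13 was 18.2 in wild type, 18.3 in ia03 and 16.5 in ju145. That of gcy-35, a soluble guanylate cyclase gene, was 1.01 in wild type, 0.686 in ia03 and 0.240 in ju145. Below that floor, and looked at only after their values were seen, 3 related cyclase genes were lower in both mutants with a q-value under 0.05 in both of the authors' deposited tables, which compare 2 libraries each. The FPKM of gcy-32 was 0.838 in wild type, 0.0403 in ia03 and 0.0572 in ju145, and that of gcy-36 was 0.764, 0.103 and 0.0848. The FPKM of gcy-37 was 0.997 in wild type and 0.224 in ju145, and it was listed at 0 in ia03. Also lower in both mutants was gcy-33, at 0.980 in wild type, 0.177 in ia03 and 0.117 in ju145. The rest of the list below the floor was mixed or too low to compare. The authors' deposited tables gave gcy-33 a q-value under 0.05 in ju145 only, and gcy-31, gcy-34, glb-5, npr-1, tax-2 and tax-4 in neither. Of these, gcy-34, tax-2 and tax-4 had status NOTEST for both mutants, and glb-5 for ju145, so the lack of a low q-value there decides nothing. As deposited, gcy-34, glb-5, tax-2 and tax-4 were above wild type in ia03, and npr-1 and tax-2 in ju145.

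In ju145, 200 genes were at least 2-fold higher and 520 at least 2-fold lower than wild type, of 14686 genes measured. Higher genes made up 27.8% of these as deposited, 41.9% after rescaling by the median ratio and 44.2% after rescaling by the upper quartile. Among coding genes and pseudogenes of at least 300 nt the counts were 57 and 291. Of the 30 lists with a percentile, 13 lay outside the central 95%.

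The third comparison took genes that differed from wild type the same way in both mutants. A pair of catalase genes and 1 insulin-like gene stood among those higher. The FPKM of ctl-1, a cytosolic catalase gene on chromosome II, was 7.08 in wild type, 32 in ia03 and 29.1 in ju145, and that of its neighbour ctl-3 was 5.25, 17.6 and 15.8, while the third gene of the cluster, ctl-2, had 77.2, 73.1 and 66.6. The similar sequences of these genes leave the split of reads among them uncertain. The insulin-like gene ins-35 had 3.81, 30.1 and 17, the arginine kinase gene argk-1 had 8.95, 35.3 and 23.2, and the collagen gene col-176 had 33.5, 113 and 82.0. Among genes that were lower, the neuropeptide-like gene nlp-20 had 145.4 in wild type, 9.10 in ia03 and 9.88 in ju145. The insulin-like gene ins-21 had 10.3 in wild type and was listed at 0 in both mutants. The zinc finger gene him-8, which acts in meiotic pairing of the X chromosome, had log2 ratios of -3.73 in ia03 and -2.35 in ju145. The F-box gene fbxa-192 had 11.3, 0.381 and 3.24, ZK354.3 had 36.2, 10.3 and 10.5, and hsp-70 had 24.7, 11.2 and 11.4. The insulin-like list as a whole was low in ia03 (median -0.40, percentile 0.01) and in ju145 (relative median -0.26, percentile 0.195), and lay at percentiles 5.70 and 6.56 when genes needed an FPKM of at least 5. With no filter on low values its median in ia03 was -0.16, at percentile 2.65, inside the central 95%. In all, 8 lists lay outside the central 95% on the same side in both mutants.

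By the size rule, 61 genes were higher and 309 lower in both mutants, of 14680 genes. The corresponding counts were 24 and 115 among coding genes and pseudogenes of at least 300 nt. Among these 14680 genes, whose status was OK in both tables, 261 were higher in ia03 and 98 in ju145, and 630 and 519 were lower. Independent lists of those sizes would share 1.74 higher and 22.3 lower genes. The log2 ratios of the 2 mutants correlated across genes at 0.736 (Pearson) and 0.650 (Spearman), where genes are not independent replicates. Both ratios share the same wild type library, and 3 simulated libraries with no effect shared by the mutants gave a correlation of 0.50, which that design sets by itself. They gave 80.7 genes higher and 81.3 lower in both on average. The simulated spread of a gene came from 1 difference between the mutants, so it includes any real difference between the alleles. That can raise the simulated counts. The observed counts became 76 higher and 237 lower after rescaling by the median ratio, and 80 and 230 by the upper quartile. Among the longer coding genes and pseudogenes the simulated counts were 49.5 and 49.1, independent lists, again sized among genes that could be compared in both, would share 0.737 and 7.16, and the correlation was 0.665 against a simulated 0.501. The covariance was 0.30 against a simulated 0.115, a difference of 0.185, and in the longer coding genes and pseudogenes it was 0.117 against 0.0614. With 1 wild type library the controls cannot be split, so part of any excess may come from that library. As deposited, among all genes only the lower ones exceeded the simulated count, and the higher ones did not. No counts were simulated under either rescaling. A gene listed at 0 in both mutants has almost no spread in the simulation, so it can hardly reach 2-fold there. Part of the excess of lower genes is thus built in. The 12 lowest genes in both mutants under the fixed rule were all of that kind. With ia03 taken as the odd library 208 genes differed from both others the same way, and with ju145 taken so 91 did, against 370 for wild type. These counts are not on equal terms, because requiring status OK for both mutants removed mostly genes higher in 1 mutant.

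**Figure D3:**
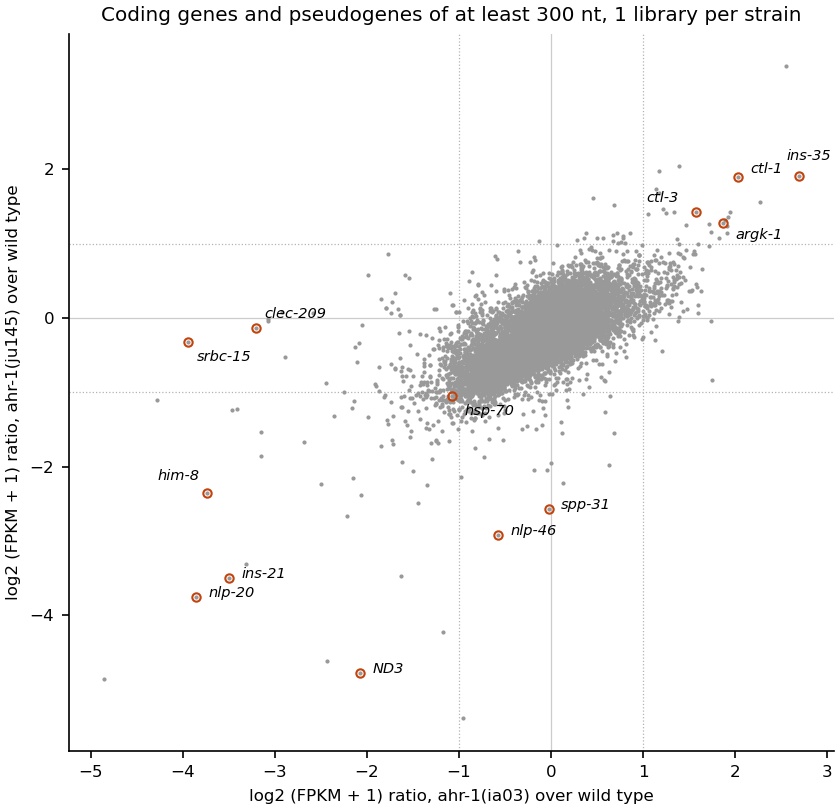
Log2 ratio of FPKM + 1 to wild type in the ia03 library (horizontal) and the ju145 library (vertical) for coding genes and pseudogenes of at least 300 nt, 1 point per gene, with dotted lines at 2-fold and named genes circled. The gene nlp-20 lies at -3.86 and -3.75, and ctl-1 at 2.03 and 1.89.

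The fourth comparison set the mutants against each other. Genes at the left of chromosome V were lower in ia03 than in either other library. In a span chosen after the values were seen, from 2345675 to 2502425, 15 of 19 measured genes were at least 2-fold below wild type in ia03 and none were in ju145, with medians of -1.65 and 0.040. The C-type lectin gene clec-209 had 389 in wild type, 41.3 in ia03 and 353 in ju145, and the transporter-related gene mct-1 had 114, 35.5 and 125. The pseudogene srbc-15 had 14.3 in wild type, was listed at 0 in ia03 and had 11.3 in ju145. Of these 19 genes, 17 share their name in the annotation with another copy, so reads cannot be assigned to single copies with certainty.

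Mitochondrially encoded genes were lower in ju145. All 14 were below wild type in ju145, 8 of them at least 2-fold, with a median log2 ratio of -1.45, while 5 were below wild type in ia03, where the median was 0.16. ND2 had an FPKM of 107 in wild type, 117 in ia03 and 22.3 in ju145, and ATP6 had 5262, 4698 and 1862. The least different was COX1, with 3061, 5732 and 2572. The share of summed FPKM in mitochondrially encoded genes was 1.69% in wild type, 2.45% in ia03 and 0.983% in ju145. That fall in ju145 is smaller than the median over genes. ND3 had 1163, 275 and 41.5, and shares its stretch of the mitochondrial genome in the files with ND5, at 585, 629 and 221, as ATP6 does with ND1, so reads may be split between them. Between the mutants 184 genes were at least 2-fold higher and 198 lower in ia03 than in ju145, against 998 and 504 at 1.5-fold and 29 and 71 at 4-fold. Higher genes made up 48.2% of these as deposited, 34.2% after rescaling by the median ratio and 33.1% by the upper quartile. Among coding genes and pseudogenes of at least 300 nt there were 132 higher and 88 lower.

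**Figure D4:**
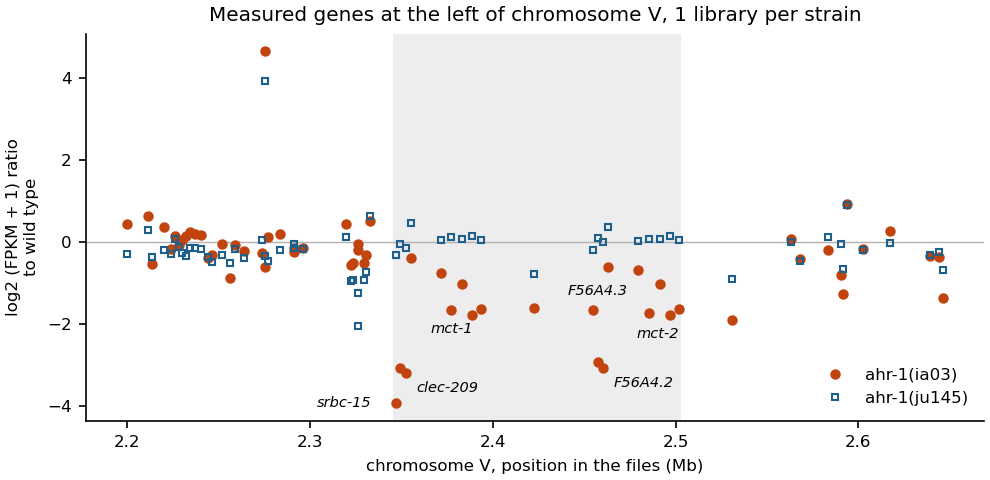
Log2 ratio of FPKM + 1 to wild type for each measured gene along the left of chromosome V (position in the files, Mb), in the ia03 library (circles) and the ju145 library (squares); the shaded span holds the 19 genes described. In it 15 genes lie at or below -1 in ia03 and none in ju145.

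**Figure D5:**
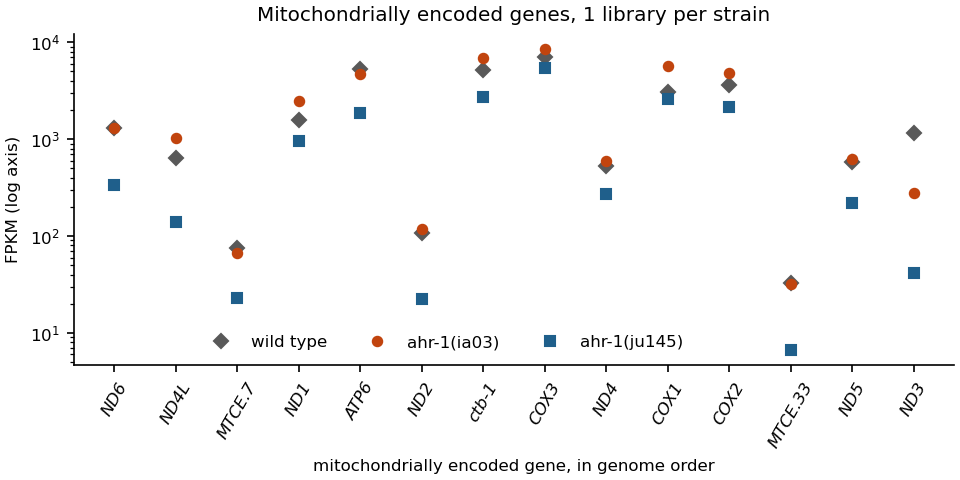
FPKM on a log axis of the 14 mitochondrially encoded genes in genome order, 1 point per library. The ju145 library has the lowest value for all 14.

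Non-coding RNAs and short features made up much of the size differences. Of 380 measured non-coding RNAs, 106 were at least 2-fold higher and 186 lower in ia03, and of 374 in ju145, 102 were higher and 160 lower. Genes with up to 200 nt of exon had median log2 ratios of -1.97 in ia03 and -1.14 in ju145, while those above 2000 nt had 0.00 and -0.19. The naming rule fixed before the data were examined took mostly such features: of its 12 lowest and 12 highest in ia03, 23 had under 300 nt of exon and all 24 were listed at 0 in at least 1 library. For example, mir-392 had an FPKM of 751 in wild type and was listed at 0 in both mutants. The share of summed FPKM in features annotated as ncRNA, snoRNA, snRNA or miRNA, of any length, was 9.82% in wild type, 4.67% in ia03 and 4.93% in ju145. Single abundant features weigh heavily in this share, such as the ncRNA F56D12.10, at 67469 in wild type, 18630 in ia03 and 18468 in ju145. The ncRNA features that overlap vit-3 and vit-4 are also counted in it. The share therefore does not measure short RNAs in general.

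The authors' deposited table for ia03 listed 906 features with a q-value under 0.05, of which 331 were higher and 575 lower than wild type. The authors' deposited table for ju145 listed 1419, of which 149 were higher and 1270 lower. These q-values compare 2 libraries, not 2 conditions. With a difference of over 2-fold on FPKM without the pseudocount, and values above 0 in both libraries, the authors' deposited tables gave 516 features for ia03 and 528 for ju145. The authors' deposited tables shared 139 of these, of which 14 were higher and 125 lower in both. That scale also counts low genes that the size rule on FPKM + 1 leaves out. By the authors' deposited tables, 78 of the 139 longer coding genes and pseudogenes that met the size rule in both mutants had a q-value under 0.05 in both. By the authors' deposited tables nlp-20, ctl-1, ctl-3, ins-35, argk-1, col-176, hsp-70, fbxa-192 and ZK354.3 had a q-value under 0.05 in both, while him-8 (0.332 in ia03 and 0.748 in ju145) and ins-21 (0.243 and 0.196) had one in neither. In the authors' deposited tables the q-value of grl-32 in ia03 was 0.529 and that of nlp-46 in ju145 was 0.152. Of the 24 extremes of the fixed rule in each mutant, the authors' deposited tables gave 0 in ia03 and 1 in ju145 a q-value under 0.05.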

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

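Both items in this part were singled out only after the values were seen. In the ia03 and ju145 libraries, 2 genes met the size rule in opposite directions against wild type, a difference that was not tested. T13H2.9, a non-coding RNA on chromosome X, had a log2 ratio of -2.88 in ia03 and 1.03 in ju145. It was listed at 0 in ia03, so the size of the ratio there depends on the pseudocount. Y74C9A.6, a small nucleolar RNA on chromosome I, had a log2 ratio of -5.29 in ia03 and 1.57 in ju145. It too was listed at 0 in ia03, so the size of that ratio also depends on the pseudocount. Both are under 200 nt long.

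Features whose status was FAIL in both deposited tables were left out of the comparisons. Of 336 such features with an FPKM of at least 1, 4 were at least 2-fold from wild type the same way in both mutants. The furrow collagen gene dpy-7 had an FPKM of 54.5 in wild type, 161 in ia03 and 111 in ju145, and nssp-6 had 4.62, 1.59 and 1.37. The non-coding RNA K02B12.12 was listed at 0 in wild type with 33.6 in ia03 and 29.7 in ju145, and Y37E3.28 had 44.5 in wild type and was listed at 0 in both mutants.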

How the results depend on the processing

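No paired analysis was possible because each strain gave 1 library. The alternatives restricted to longer coding genes and pseudogenes, and to genes above 0 in all libraries, were chosen after seeing the data, as were other size limits between the mutants. In each comparison as deposited and under each rescaling, more genes were lower than higher against wild type. Leaving out the filter on low values could not change a count, since a gene under FPKM 1 cannot reach 2-fold on this scale, but it moved the insulin-like list in ia03 inside the central 95% of random lists, to a median of -0.16 and percentile 2.65. Where a count below moved by over 1.5 times, the cause was not tested unless the alternative itself gives it. A smaller or larger size limit counts more or fewer genes by construction. At 1.5-fold, 987 were higher and 1951 lower in ia03, 432 and 2024 in ju145, 190 and 1253 in both, and 998 and 504 in ia03 against ju145. At 4-fold these were 112 and 190, 104 and 147, 21 and 99, and 29 and 71, so which direction held more genes between the mutants changed with the size limit. A pseudocount of 5 shrinks low genes and gave 151 and 362 in ia03, 104 and 247 in ju145, 25 and 178 in both, and 53 and 104 between mutants. A pseudocount of 0.1 gave 849 lower in ju145, 123 higher in both, and 435 higher and 312 lower between mutants. A floor of FPKM 5 left 123 higher in ju145. Rescaling left 345 (median ratio) and 329 (upper quartile) lower in ju145. All features whatever their status gave 300 higher and 302 lower between mutants. Longer coding genes and pseudogenes gave 225 and 343 in ia03, 57 and 291 in ju145, 24 and 115 in both, and 88 lower between mutants. Genes above 0 in all libraries gave 217 higher in ia03, 52 higher in ju145, 23 higher and 173 lower in both, and 116 lower between mutants. Without stage-dependent lists, which removes 6 lists, 8 lists lay outside the central 95% of random lists in ia03 and 8 in ju145. By the authors' deposited tables, a q-value limit of 0.01 left 395 features in ia03 and 557 in ju145, and a limit of 0.05 together with the size rule left 411 and 279. Of 193 named values of at least 2-fold, 184 stayed so after rescaling by the median ratio and 105 with a pseudocount of 5. None reversed, but these alternatives could not turn the sign of a value of that size, so the absence of reversals says nothing about robustness. The sign of the list median changed with rescaling for 15 of 31 lists in ju145 and 3 in ia03. With no counts and no replicates, the limits set by depth could not be measured.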

Other observations

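Some gene groups outside the comparisons above stood apart; these were chosen after their values were seen. At the right of chromosome V the neighbouring F-box gene fbxa-192 and the pseudogenes fbxa-191 and fbxa-193 were lower in both mutants, and most so in ia03. The FPKM of fbxa-191 was 4.12 in wild type, 0.145 in ia03 and 1.21 in ju145, and that of fbxa-193 was 5.58, 0.211 and 2.59. The gene cylc-2, which the files place in the same stretch as ahr-1, had 112 in wild type, 48.6 in ia03 and 49.5 in ju145. In ju145, 1 window of 10 consecutive genes, in a histone cluster on chromosome II from 13819557 to 13827640, had a median log2 ratio of 0.66, above the highest of 1000 shuffles of gene order (0.53). Its near-identical copies share reads, and his-10, his-14 and his-26 had the same FPKM of 8.40 in wild type and 15.9 in ju145.

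Tests of the chromosome V run, of the longer coding genes, and of the scaling and single-gene explanations for mitochondrial genes were chosen only after the results were seen. The first pattern is the 370 genes that differed from wild type in both mutants. Taking wild type as the odd library gave 1.78 times the largest count with a mutant as the odd library, past the bound of 1.5 set before the data were examined, but 1.31 times among longer coding genes and pseudogenes. That bound assumed libraries that vary alike, and the excess lies largely in short RNAs. Requiring status OK for both mutants also cut the higher genes from 372 to 261 in ia03 and from 200 to 98 in ju145. The lower genes stayed at 630 in ia03 and went from 520 to 519 in ju145. This removal of genes higher in 1 mutant can lower the counts with a mutant as the odd library, and so raise the ratio by itself. A wild type library that itself stands apart therefore cannot be told apart from an effect of losing ahr-1. Chromosome I, where ahr-1 lies, held 17.8% of the genes (exact binomial 95% interval 14.1 to 22.1%) against 16.3% of measured genes. The genes were thus not gathered on that chromosome as a whole. This share does not look at the stretch near ahr-1, treats genes as independent, and counts many short RNAs that could hide a linked block. Linked variants near ahr-1 therefore stay open. Stage-dependent lists held 1.35% of them (0.440 to 3.13%) against 2.69%, but a gene enters that share only if it was 2-fold from wild type in both mutants, and in ju145 the medians of major sperm proteins, other sperm genes and vitellogenins, before adjustment for the median of all genes, were -0.37, -0.56 and -0.58, so the bound set beforehand could miss a smaller shift and a difference in developmental timing stays open.

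The second pattern is the run of lower genes on chromosome V in ia03. The lowest median over 10 consecutive genes was -1.69, below the lowest of 1000 shuffles of gene order (-1.11), and -1.65 against -0.97 with 1 copy of each name. Sharing reads between copies keeps their sum, yet the summed copies had a median log2 ratio of -1.75. The median in ju145 was 0.040, which argues against an effect common to both alleles. Whether the alleles remove ahr-1 function to the same degree was not measured. A deletion or other variant of the ia03 strain is a candidate explanation that was not tested here.

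The third pattern is the low mitochondrial transcripts of ju145. The median stayed at -1.25 after rescaling, because the median of all genes in ju145 was only -0.18. A scaling common to all genes therefore does not account for it. With 14 of 14 genes below wild type, the difference was not confined to 1 gene. These values cannot speak to a single variant that lowers all of them. Nuclear genes of the respiratory chain (39 measured, listed before the test) had a median of 0.24 relative to all genes, at percentile 95.2, so a loss of mitochondria that lowers those genes too is not supported. Base composition and RNA handling of this library were not tested and stay open, as does an effect of the allele or strain.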
